A study of Mus musculus with 28 samples.

How the data were processed

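RNA was measured in single whole mouse embryos of the CD1 strain at the morula and blastocyst stages. Per the labels' protocols, complementary DNA was made from polyadenylated RNA with a SMART-Seq ultra low input kit, which copies full-length transcripts from very little material, and was sequenced on an Illumina HiSeq instrument. Per the submitters' processing notes, cutadapt 1.14, Bowtie2 2.2.9 and RSEM 1.3.1 were used with the mouse builds GRCm38 and mm10. The notes give neither the role nor the order of these tools, and whether strand was used in counting is not given in the sources used here. The kit does not mark strand, so reads of a gene and of its antisense partner cannot be told apart, and reads of pseudogenes and paralogs are uncertain where RSEM could split them between near-identical copies.

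The authors deposited 1 table of log2 values per stage. The values behaved as log2 counts per 1000000 reads (CPM) with an offset of 0.5 reads added before the logarithm, and each table had been scaled on its own. Removing the offset gave whole reads for 100% of the values of both tables within a tolerance of 0.01 reads, and this recovered the read total of every embryo. The blastocyst table held 15582 genes, of which 15575 matched a symbol and a position in the GENCODE M21 annotation of GRCm38. The morula table held 16745 genes, of which 16731 matched. The blastocyst table also held 3 entries that name no mouse gene, LacZ, Neomycine and Puromycin. These took at most 0.0114% of the reads of an embryo, stayed out of every test across genes and are described apart.

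The labels describe 28 samples, and 27 of them had a column. The library labelled as a repeat of blastocyst het 3 in the other sequencing batch was not analysed here. Column names were matched to samples by the prefix and number in the brackets of the sample titles, and 0 columns belonged to other samples. Groups and embryo numbers came from the sample titles. The titles also carry a prefix. MZ_KO and M_KO blastocysts share the prefix C7, WT_flfl and het blastocysts share N89, MZKO morulae carry C50, and del and het morulae share N2. The sequencing batch given in the labels is the same for all 14 blastocysts and differs from that of all 13 morulae, so batch and stage cannot be told apart. Nothing in the labels says which embryos share a mother or were collected on separate days. The p-values therefore measure only the spread between these embryos. Within every group, pairs of embryos differed far beyond sampling noise, with a chi-square per degree of freedom of at least 36.9. That test covers counting error only and cannot exclude separate libraries of 1 embryo, so the embryos were counted as separate because the labels give them so.

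The design had assumed linear normalized counts. Because the tables held log2 values, CPM was recovered by undoing the logarithm and taking off the offset, and tests were run on log2(CPM + 1). A fold change on this scale understates the change of genes near 0. Genes with at least 10 CPM in at least 3 embryos of a table were tested, which left 9585 genes in blastocysts and 9953 in morulae. Group means were fitted with limma 3.58.1 in R 4.3.3, all groups of a stage in 1 fit, with a trended moderated variance. Tests were two-sided, p was adjusted by the Benjamini-Hochberg method over the genes tested in a comparison, and an adjusted p under 0.05 counted as a change, with no fold threshold. All 9 comparisons were made this way. The last compared the MZ knockout effect against het between the stages, over 8572 genes that passed the filter in both tables, and each effect was taken within its own table. Single values such as the Ctcf level were compared by exact two-sided permutation tests over all splits of the embryos. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. Group values below are mean ± SD in CPM. CPM and every share given in percent of reads, above and below, are relative to the scaled library size of an embryo. That size was between 0.935 (morula het 7) and 1.17 (morula MZKO 1) times the read total.

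Gene groups were 31 lists written from textbook knowledge, covering oxidative phosphorylation, mitochondrially encoded transcripts, glycolysis, pyruvate and the tricarboxylic acid cycle, the mitochondrial ribosome, mitochondrial protein import, fatty acid oxidation, cholesterol synthesis, nucleotide and one-carbon synthesis, nutrient transporters, cytosolic ribosomal proteins, ribosome biogenesis, the proteasome, p53 targets, the integrated stress and unfolded protein response, immediate early and heat shock genes, DNA replication, mitosis, trophectoderm, epiblast and primitive endoderm markers, cavitation and junctions, oocyte transcripts, 2-cell transcripts, cohesin and CTCF-associated proteins, clustered protocadherins, imprinted genes, markers of granulosa, oviduct and blood cells, and Y-linked genes. Lists with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the lists of a comparison. Camera with an estimated correlation and limma's fry were the alternatives. Of the 56 list calls over all comparisons, 0 held with an estimated correlation and 15 held with fry, which asks whether the genes of a list move one way on balance. Camera at the preset correlation called 56 with 0 lost at a pseudocount of 5, so the list calls rest on the assumption that genes of a list vary nearly independently between embryos.

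Genes were named by a fixed rule. It took Ctcf, then per comparison the 6 largest rises and 6 largest falls among changed genes whose groups do not overlap and whose higher mean is at least 100 CPM, passing over predicted genes and pseudogenes. With fewer than 30 changed genes it took up to 12 by adjusted p. It also took up to 4 members of each list by p and a panel of lineage genes. Some genes that the rule took are not reported here. The groups, tests, lists, this rule and most alternatives were set before the data were examined. The alternatives were pseudocounts of 0.5 and 5, no filter or a minimum of 50 CPM, quantile normalization, weights per embryo, a covariate from Y-linked genes, fits of only the groups compared, other control means, the embryo number as a block, and leaving out each embryo in turn. Others were added afterwards, namely the log2 values as deposited, limma-voom on the recovered reads, a minimum of 1 CPM, leaving out embryos with much haemoglobin RNA, a block for the numbers that end the column names, and leaving out pseudogenes.

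The fit was tested on simulated reads drawn from the real means and library sizes, with 200 genes changed. These were taken only from genes with at least 50 CPM in at least 3 embryos, so the shares below do not cover genes with less expression. In the simulation of blastocyst MZ_KO against WT_flfl, over 9504 genes, 51% of the 2-fold and 95% of the 4-fold changes were found. In that of morula MZKO against het, over 9913 genes, these shares were 16% and 80%. For the difference between stages, over 8430 genes, they were 9.09% and 66.3%. The precision of morula comparisons was therefore lower than that of blastocyst comparisons. Camera called a simulated list of 40 genes shifted by 0.5 on the log2 scale and did not call an unshifted list. Genes were simulated independently of each other, so this says nothing of lists whose genes vary together. Y-linked genes were used as a covariate only, since 3 of them were tested in blastocysts and 2 in morulae, too few for a list test. Clustered protocadherins had 0 members tested.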

Results

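RNA was measured in 27 single mouse embryos, 14 blastocysts and 13 morulae. The series title frames the study around chromatin folding and a change of metabolism at the passage from morula to blastocyst that needs CTCF, the zinc finger protein that binds insulators and halts cohesin loops. Blastocysts came as WT_flfl (n = 3), het (n = 4), M_KO (n = 4) and MZ_KO (n = 3), and morulae as het (n = 3), del (n = 4) and MZKO (n = 6). The labels do not spell these codes out. In this field M commonly stands for loss of the maternal store and MZ for loss of both the maternal and the zygotic gene product, and what del stands for is not given. Read totals lay between 7377302 (M_KO 1) and 27883060 (het 8) in blastocysts. In morulae they lay between 12136606 (MZKO 8) and 20414013 (MZKO 1), apart from del 6 with 1635553 reads. Between 12158 genes (del 6) and 16343 genes (MZKO 1) were detected per embryo, so the values of del 6 rest on the least depth. The Y-linked genes Ddx3y and Eif2s3y both reached 10 CPM in 2 of 3 MZ_KO, 2 of 4 M_KO, 1 of 3 WT_flfl and 3 of 4 het blastocysts, and in 3 of 6 MZKO, 1 of 4 del and 0 of 3 het morulae.

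Ctcf itself was nearly absent from MZ_KO blastocysts and from both morula groups with a knockout or del label. The gene (ENSMUSG00000005698) lies on chromosome 8 from 105636568 to 105682922 on the plus strand of GRCm38. It stood at 95.1 ± 6.02 CPM in WT_flfl, 67.5 ± 9.73 CPM in het, 69.5 ± 15.6 CPM in M_KO and 3.62 ± 0.660 CPM in MZ_KO blastocysts (SD, n = 3, 4, 4 and 3). In morulae it stood at 38.6 ± 14.6 CPM in het, 4.33 ± 3.60 CPM in MZKO and 2.30 ± 2.68 CPM in del (SD, n = 3, 6 and 4), and del 4 and MZKO 8 had 0 reads. No embryo labelled MZ_KO, MZKO or del reached the level of any embryo of the other groups in its table. MZ_KO was lower than WT_flfl by an exact permutation test at p = 0.1, the smallest two-sided p that 3 against 3 embryos allow, and lower than het and than M_KO at p = 0.0286 each. Morula MZKO was lower than het at an exact permutation p = 0.0119 and del was lower than het at an exact permutation p = 0.0286. MZKO and del did not differ past the threshold (exact permutation p = 0.352). Blastocyst het was below WT_flfl at an exact permutation p = 0.0286 and M_KO below WT_flfl at an exact permutation p = 0.0571. Reads were counted over the whole gene model, and which part of Ctcf the deletion removes is not given, so the level cannot tell a shortened transcript from a missing one. The 2 tables were scaled separately, and levels were tested only within a table.

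**Figure D1:**
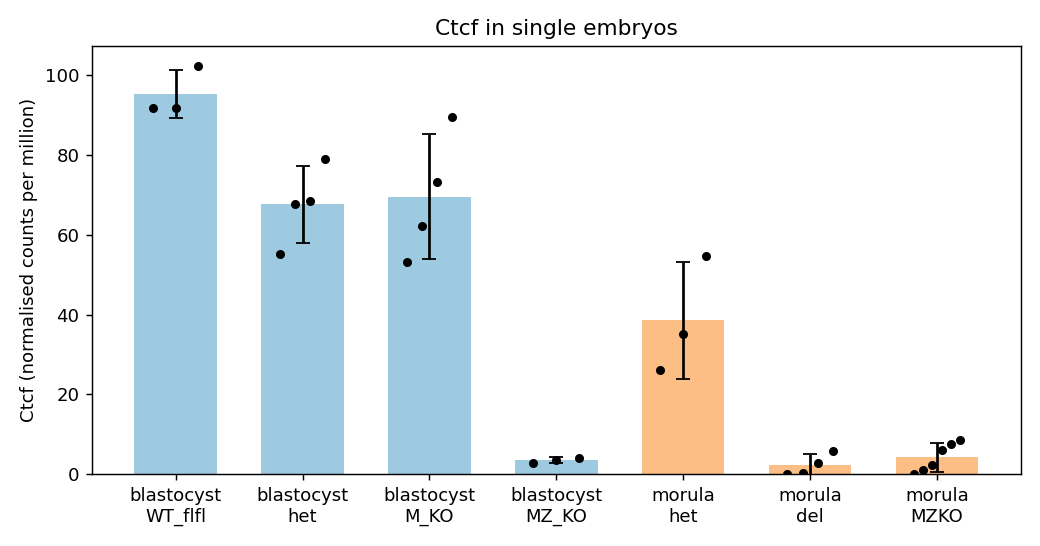
Ctcf in CPM, normalised counts (vertical axis), in each embryo (points), with the mean (bar) and SD (error bar) of each blastocyst and morula group. MZ_KO blastocysts sit between 2.92 and 4.23, and all WT_flfl, het and M_KO blastocysts at or above 53.2; the stages were scaled separately.

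The blastocyst table also held 3 entries that name no mouse gene but bacterial reporter or resistance genes. LacZ, which encodes beta-galactosidase, stood at 0.543 ± 0.862 CPM in WT_flfl, 28.0 ± 5.74 CPM in het, 25.7 ± 14.7 CPM in M_KO and 83.1 ± 32.9 CPM in MZ_KO (SD, n = 3, 4, 4 and 3). MZ_KO was above het and above M_KO at an exact permutation p = 0.0286 each, and above WT_flfl at p = 0.1, the smallest an exact test can give there. Neomycine stood at 25.6 ± 6.71 CPM in WT_flfl, 9.17 ± 3.34 CPM in het, 7.81 ± 0.897 CPM in M_KO and 0 CPM in MZ_KO. Puromycin stood at 23.4 ± 6.47, 7.06 ± 2.502, 11.9 ± 5.78 and 0.139 ± 0.241 CPM in the same order. What these entries mark is not stated in the labels, and they entered no test across genes.

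**Figure D2:**
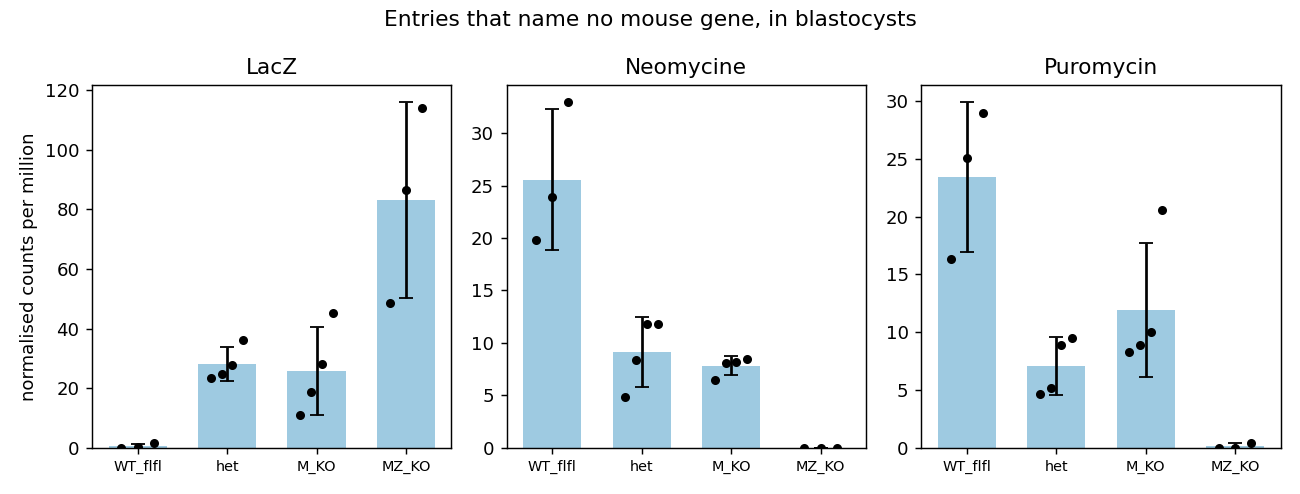
LacZ, Neomycine and Puromycin in CPM (vertical axes) in each blastocyst (points), with group means (bars) and SD (error bars). LacZ averaged 0.543 in WT_flfl and 83.1 in MZ_KO, while Neomycine averaged 25.6 in WT_flfl and 0 in MZ_KO.

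Blastocyst MZ_KO against WT_flfl asks what differs when Ctcf is lost, and single genes fell steeply. Enpep, glutamyl aminopeptidase of the cell surface, fell from 298 ± 47.2 to 3.69 ± 3.46 CPM (log2 fold change −6.43, SE 0.54, adjusted p = 1.41e-06; chromosome 3, 129269175 to 129332720). Gfm1, a mitochondrial translation elongation factor, fell from 167 ± 24.4 to 5.82 ± 7.09 CPM (−5.31, SE 0.57, adjusted p = 2.19e-05; chromosome 3, 67430096 to 67476529). Fabp5, a fatty acid-binding protein, fell from 206 ± 12.6 to 7.47 ± 2.68 CPM (−4.67, SE 0.28, adjusted p = 3.51e-08; chromosome 3, 10012548 to 10016607). Adh1, an alcohol dehydrogenase, fell by 5.06 on the log2 scale (SE 1.11, adjusted p = 0.00679; chromosome 3, 138260991 to 138290698). Ndrg1, a gene responsive to stress and differentiation, fell by 4.21 (SE 0.60, adjusted p = 2.76e-04; chromosome 15, 66929318 to 66969640). Adprhl2, which removes ADP-ribose from serines, went from 123 ± 33.7 CPM to 1 read over the 3 MZ_KO embryos (adjusted p = 2.17e-11; chromosome 4, 126316047 to 126321703), so its fitted fold change depends on the pseudocount. All values are CPM with SD, n = 3 per group.

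Among the genes that the naming rule took, the largest rises in blastocyst MZ_KO against WT_flfl were smaller. Actn2, the alpha-actinin of muscle Z-discs, rose from 33.5 ± 10.95 to 199 ± 21.98 CPM (2.58, SE 0.36, adjusted p = 2.22e-04; chromosome 13, 12269426 to 12340760). Fstl3, a secreted activin antagonist, rose from 31.1 ± 12.8 to 147 ± 8.61 CPM (2.30, SE 0.37, adjusted p = 7.52e-04; chromosome 10, 79777272 to 79782630). B2m, the light chain of MHC class I, rose from 67.6 ± 5.05 to 333 ± 59.3 CPM (2.27, SE 0.37, adjusted p = 8.86e-04; chromosome 2, 122147686 to 122153083). Eif1b and Tspan3 each rose by a log2 fold change of 1.87 (SE 0.25 and 0.33, adjusted p = 1.41e-04 and 0.00140). Clec10a, a lectin known from macrophages, rose by 2.54 (SE 0.60, adjusted p = 0.0106), a call lost without WT_flfl 9 (adjusted p = 0.0558). In all, 464 of 9585 genes were higher and 801 lower, and the change was at least 2-fold for 231 of the higher and 608 of the lower genes. The count of 1265 fell to 783 without WT_flfl 7, to 828 without WT_flfl 1, and to 787 without WT_flfl 1 and het 6, the blastocysts with most haemoglobin RNA (3.43% and 3.10% of reads). MZ_KO embryos carry the title prefix C7 and WT_flfl embryos N89, so prefix and group coincide here.

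**Figure D3:**
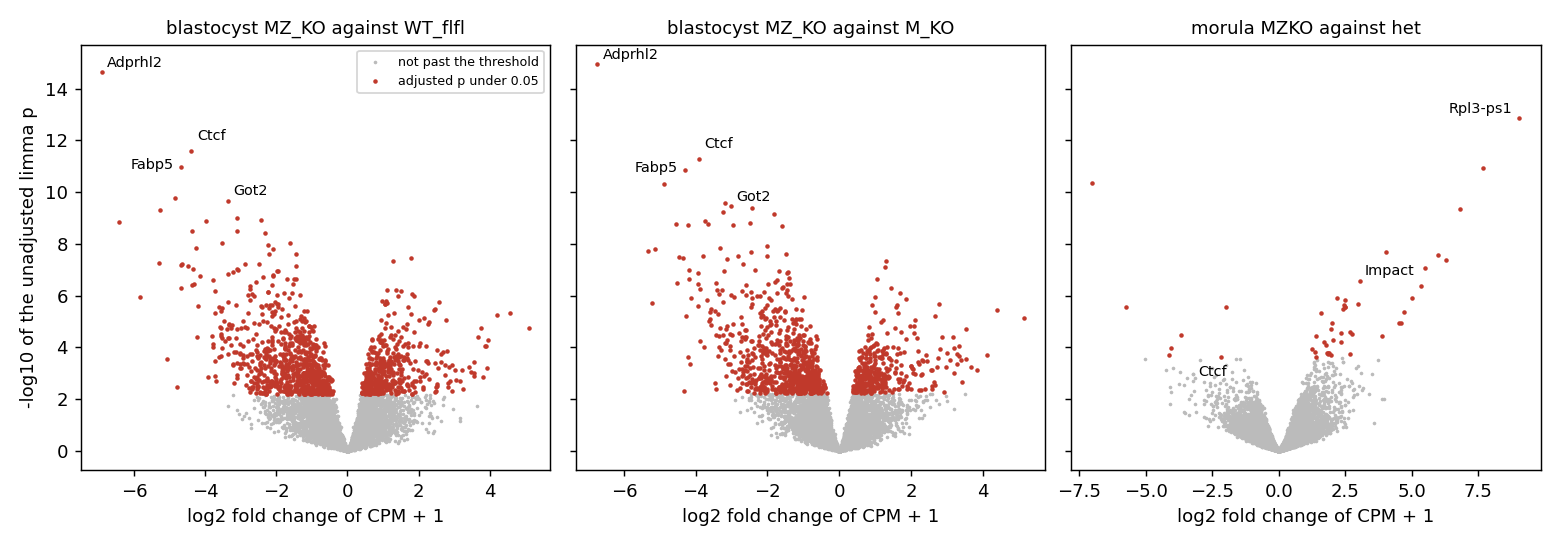
Log2 fold change of CPM + 1 (horizontal axes) against −log10 of the unadjusted limma p (vertical axis) for each tested gene (points) in blastocyst MZ_KO against WT_flfl, blastocyst MZ_KO against M_KO and morula MZKO against het, with genes at an adjusted p under 0.05 in red. Of these, 801, 775 and 7 genes were lower and 464, 358 and 41 higher; points for genes near 0 reads in a group depend on the pseudocount.

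Among gene groups, nutrient transporters and DNA replication genes were lower as sets in blastocyst MZ_KO against WT_flfl, and those of the cytosolic and mitochondrial ribosomes and the proteasome were higher. Of 13 nutrient transporters 0 rose and 3 fell (0 and 6 adjusted over the list alone), including the monocarboxylate transporter Slc16a1 (−1.30, SE 0.20, adjusted p = 5.07e-04; 239 ± 33.2 to 96.0 ± 12.9 CPM) and the glucose transporter Slc2a1 (−2.30, SE 0.47, adjusted p = 0.00412). That list was lower as a set (camera adjusted p = 0.00145, and adjusted p = 0.0890 with an estimated correlation). Of 41 DNA replication and G1/S genes 1 rose and 13 fell (1 and 15 adjusted over the list alone), among them the clamp loader subunit Rfc5 (−1.70, SE 0.20, adjusted p = 5.10e-05), Uhrf1, which recruits maintenance methylation (−1.97, adjusted p = 2.55e-04), the polymerase subunit Pold1 (−1.52, adjusted p = 7.71e-04) and the helicase subunit Mcm7 (−1.03, adjusted p = 0.00371). The set was lower (camera adjusted p = 1.07e-04, and adjusted p = 0.532 with an estimated correlation). Of 78 cytosolic ribosomal proteins 18 rose and 0 fell (33 and 1 adjusted over the list alone), such as Rps7 (0.80, adjusted p = 0.00623) and Rps27a (0.64, adjusted p = 0.00616). The set was higher (camera adjusted p = 1.91e-12, and adjusted p = 0.532 with an estimated correlation), and its summed share of reads was 3.87% ± 0.357 against 3.15% ± 0.117 (exact permutation p = 0.1, the smallest possible, SD, n = 3 per group). Of 37 proteasome genes 8 rose and 2 fell (14 and 2 adjusted over the list alone), and the set was higher (camera adjusted p = 7.92e-06, and adjusted p = 0.532 with an estimated correlation), although the regulatory subunits Psmd1 and Psmd6 each fell by 0.64 (adjusted p = 0.00732 and 0.00860). Of 77 mitochondrial ribosome genes 6 rose and 2 fell (4 and 2 adjusted over the list alone), and the set was higher (camera adjusted p = 1.20e-04, and adjusted p = 0.532 with an estimated correlation). Its members went far in both directions. Mrps16 rose from 55.1 ± 16.6 to 192 ± 27.9 CPM (1.82, adjusted p = 1.28e-04), while Mrps2 fell from 145 ± 4.12 to 9.65 ± 7.13 CPM (−3.98, SE 0.33, adjusted p = 1.37e-06) and Mrpl23 fell by 3.10 (adjusted p = 0.00111).

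The other metabolic lists did not pass as sets, but single enzymes fell. Of 75 nuclear-encoded oxidative phosphorylation genes 2 rose and 9 fell (2 and 9 adjusted over the list alone; camera adjusted p = 0.440). Ndufb7 of complex I fell from 116 ± 2.07 to 21.1 ± 3.21 CPM (−2.42, SE 0.20, adjusted p = 1.37e-06), and Ndufb10, Ndufab1 and the ATP synthase subunit Atp5g2 fell by 1.46, 1.19 and 1.41. Of 15 mitochondrially encoded transcripts 0 rose and 3 fell (0 and 3 adjusted over the list alone; camera adjusted p = 0.0784). Of 17 glycolysis genes 0 rose and 4 fell (0 and 5 adjusted over the list alone; camera adjusted p = 0.136), among them Gpi1 (−1.08, adjusted p = 0.00179) and Pkm (−0.78, adjusted p = 0.00616). Of 27 genes of pyruvate and the tricarboxylic acid cycle 3 rose and 6 fell (4 and 12 adjusted over the list alone; camera adjusted p = 0.138). Of 23 fatty acid oxidation genes 0 rose and 4 fell (0 and 4 adjusted over the list alone; camera adjusted p = 0.136), with the thiolase Acaa2 from 262 ± 27.8 to 95.1 ± 11.5 CPM (−1.45, SE 0.16, adjusted p = 2.42e-05) and the dehydrogenase Acadm (−0.73, adjusted p = 0.00616). Of 30 genes of nucleotide and one-carbon synthesis 1 rose and 8 fell (1 and 8 adjusted over the list alone; camera adjusted p = 0.0717), including the purine enzyme Gart (−1.10, adjusted p = 0.00275) and Mthfd2 (−2.30), while Phgdh of serine synthesis rose by 1.11. Of 29 protein import genes 3 rose and 2 fell (5 and 3 adjusted over the list alone; camera adjusted p = 0.163), with Tomm5 up by 1.08 and the chaperonin Hspd1 down (−0.66). Of 22 cholesterol synthesis genes 0 rose and 3 fell (0 and 3 adjusted over the list alone; camera adjusted p = 0.485).

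Lineage genes also moved in blastocyst MZ_KO against WT_flfl. Nanog, a pluripotency factor of the epiblast, rose from 152 ± 14.3 to 321 ± 100.1 CPM (1.04, SE 0.25, adjusted p = 0.0128), a call lost without MZ_KO 6 (adjusted p = 0.0638). Eomes, a trophectoderm factor, fell from 162 ± 72.3 to 48.0 ± 13.3 CPM (−1.64, SE 0.43, adjusted p = 0.0182), and the call was lost without MZ_KO 2, MZ_KO 6, WT_flfl 1 or WT_flfl 7 (adjusted p = 0.0624, 0.0603, 0.0681 and 0.0858). Gata4, of the primitive endoderm, stood at 0.848 ± 1.47 CPM against 22.6 ± 14.4 CPM (adjusted p = 0.00332), and its fitted fold change depends on the pseudocount. Cdx2 and Gata3 of the trophectoderm each had a log2 fold change of −0.60 (adjusted p = 0.156 and 0.122) and did not pass, although Cdx2 did without MZ_KO 7 or WT_flfl 9 (adjusted p = 0.0420 and 0.0265) and Gata3 without MZ_KO 7 (adjusted p = 0.0464). Pou5f1 (0.27, adjusted p = 0.341) and Gata6 (0.12, adjusted p = 0.827) did not pass, and Sox2 was too low to be tested. Of 28 trophectoderm markers 1 rose and 8 fell (3 and 13 adjusted over the list alone; camera adjusted p = 0.0717), such as the growth factor receptor Fgfr2 (−1.48) and Tspan8 (−2.45). Of 23 epiblast and inner cell mass markers 4 rose and 2 fell (4 and 2 adjusted over the list alone; camera adjusted p = 0.285). Dppa3, also called Stella, rose from 1792 ± 118 to 3813 ± 539.5 CPM (1.08, SE 0.15, adjusted p = 2.15e-04), and the secreted phosphoprotein Spp1 fell from 566 ± 129 to 69.6 ± 36.2 CPM (−3.10, SE 0.27, adjusted p = 2.51e-06). Of 17 primitive endoderm markers 0 rose and 4 fell (0 and 4 adjusted over the list alone; camera adjusted p = 0.0784), among them the laminin chain Lamb1 (−2.89, adjusted p = 0.00107). Of 41 cavitation and junction genes 0 rose and 7 fell (1 and 9 adjusted over the list alone; camera adjusted p = 0.0717), including the membrane linker Ezr (−2.29, adjusted p = 2.62e-04), the sodium pump subunit Atp1b1 (−1.01, adjusted p = 0.00706) and the catenin Ctnna1 (−0.82).

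Stress, division and maternal lists changed in single members. Of 24 genes of the integrated stress and unfolded protein response 2 rose and 7 fell (2 and 8 adjusted over the list alone; camera adjusted p = 0.142), with asparagine synthetase, Asns, from 74.3 ± 33.9 to 4.99 ± 1.84 CPM (−3.57, SE 0.53, adjusted p = 3.69e-04) and Cth of cysteine synthesis up by 1.33. Of 44 mitosis genes 8 rose and 1 fell (8 and 6 adjusted over the list alone; camera adjusted p = 0.480), such as the kinase Aurka (0.69, adjusted p = 0.00225) and the checkpoint gene Bub3 (0.81). Of 23 p53 targets 0 rose and 2 fell (0 and 2 adjusted over the list alone; camera adjusted p = 0.604), among them Gtse1 (−1.57, adjusted p = 0.00554). Of 14 immediate early and heat shock genes 0 rose and 3 fell (2 and 3 adjusted over the list alone; camera adjusted p = 0.868), including Junb (−2.51) and Hsph1 (−0.98). Of 54 ribosome biogenesis genes 2 rose and 1 fell (0 and 0 adjusted over the list alone; camera adjusted p = 0.574). Of 23 cohesin and CTCF-associated genes 2 rose and 2 fell (3 and 2 adjusted over the list alone; camera adjusted p = 0.988), with the meiotic cohesin subunit Stag3 down (−2.65, adjusted p = 0.00214). Of 23 imprinted genes 1 rose and 2 fell (1 and 4 adjusted over the list alone; camera adjusted p = 0.868), among them H13 (−1.35, adjusted p = 0.00208). Of 9 oocyte transcripts 2 rose and 1 fell (2 and 2 adjusted over the list alone; camera adjusted p = 0.241). By limma 0 genes passed among 8 transcripts of the 2-cell stage (camera adjusted p = 0.285), 8 granulosa markers (0.142), 8 oviduct markers (0.899) and 12 blood markers (0.908), with 0 adjusted over the list alone in each. The median, mean and set test differed in sign for ribosome biogenesis (median 0.03, mean −0.02, test higher), mitosis (−0.02, −0.05, higher), epiblast markers (0.09, −0.01, higher), cohesin (0.08, −0.23, higher) and immediate early genes (0.10, −0.15, lower).

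**Figure D4:**
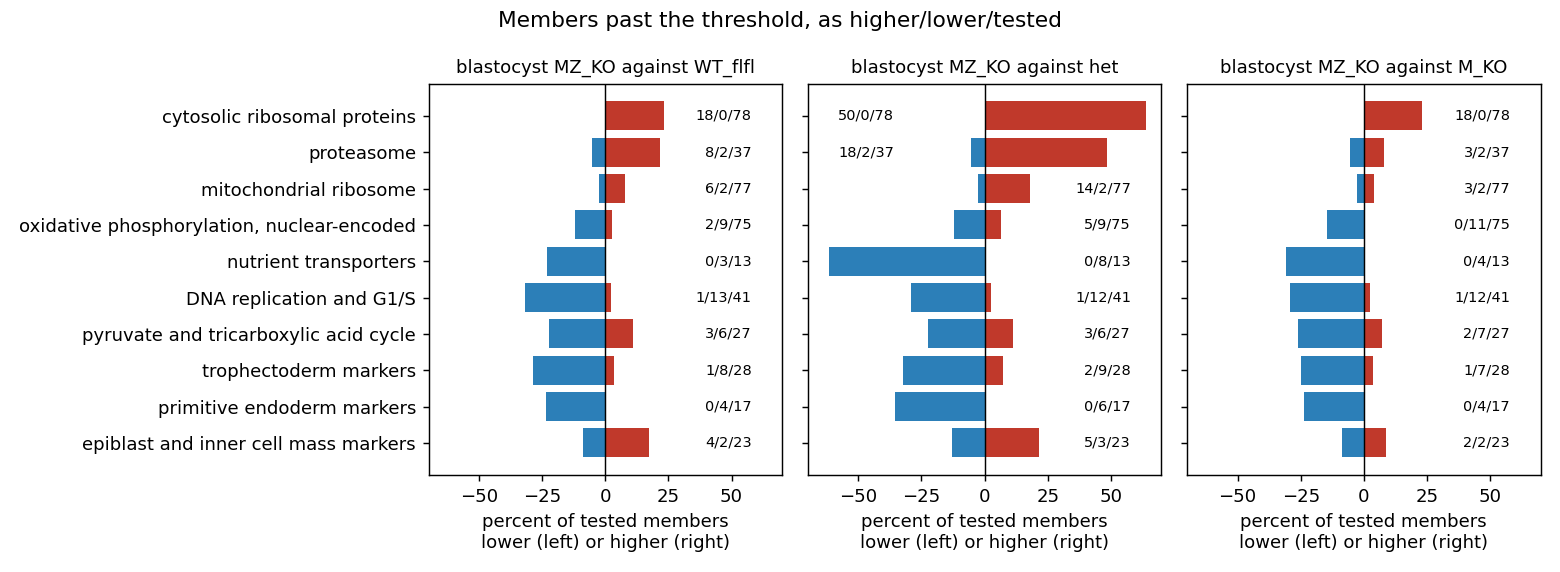
Percent of tested members of 10 gene lists (vertical axis) that were lower (blue, left) or higher (red, right) at an adjusted p under 0.05 in blastocyst MZ_KO against WT_flfl, against het and against M_KO, with the counts as higher/lower/tested. Of 78 cytosolic ribosomal protein genes 18, 50 and 18 were higher and 0 lower; no set call held with an estimated correlation.

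Blastocyst MZ_KO against het compared the knockout with embryos that had an intermediate Ctcf level. Enpep fell by 6.21 on the log2 scale (SE 0.50, adjusted p = 9.50e-07), Gfm1 by 5.30 (SE 0.53, adjusted p = 7.74e-06), and Fabp5 by 4.33 (SE 0.27, adjusted p = 4.03e-08). Ndrg1 fell by 3.85 (SE 0.56, adjusted p = 2.88e-04). Fstl3 rose from 20.99 ± 7.71 to 147 ± 8.61 CPM (2.81, SE 0.34, adjusted p = 5.28e-05). Ccne1, cyclin E1, rose from 104 ± 52.0 to 393 ± 17.4 CPM (2.05, SE 0.35, adjusted p = 0.00106; chromosome 7, 38097984 to 38107534). The small GTPase Rab29 rose from 39.1 ± 4.86 to 152 ± 6.13 CPM (1.94, SE 0.23, adjusted p = 3.37e-05; chromosome 1, 131867224 to 131872887; SD, n = 4 and 3). Eomes fell (−2.03, adjusted p = 0.00260), as did Sox17 of the endoderm (−2.24, SE 0.54, adjusted p = 0.00945), while Nanog rose (1.25, adjusted p = 0.00210). Gata4 stood at 0.848 ± 1.47 against 29.7 ± 30.1 CPM (adjusted p = 0.00144). Altogether 673 genes were higher and 1038 lower in blastocyst MZ_KO against het. The count of 1711 fell to 1072 without MZ_KO 2 and to 1013 without WT_flfl 1 and het 6, which had much haemoglobin RNA, and the prefixes again differ between the groups. Under quantile normalization the median log2 fold change over all genes went from −0.06 to 0.04, and 48.4% instead of 39.3% of the called genes were higher.

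Sets moved as follows in blastocyst MZ_KO against het. Of 78 cytosolic ribosomal proteins 50 rose and 0 fell (60 and 0 adjusted over the list alone; camera adjusted p = 1.91e-22, and adjusted p = 0.436 with an estimated correlation), and their summed share of reads was 3.87% ± 0.357 in MZ_KO against 2.88% ± 0.334 in het (exact permutation p = 0.0571, SD, n = 3 and 4). Of 37 proteasome genes 18 rose and 2 fell (25 and 2 adjusted over the list alone; camera adjusted p = 2.40e-09, and adjusted p = 0.436 with an estimated correlation). Of 77 mitochondrial ribosome genes 14 rose and 2 fell (21 and 2 adjusted over the list alone; camera adjusted p = 3.96e-07). Of 29 protein import genes 7 rose and 2 fell (9 and 2 adjusted over the list alone; camera adjusted p = 0.0465, and 0.109 under quantile normalization). Both had an adjusted p = 0.520 with an estimated correlation. Of 13 nutrient transporters 0 rose and 8 fell (0 and 9 adjusted over the list alone; camera adjusted p = 7.54e-04, and adjusted p = 0.0613 with an estimated correlation). Of 41 DNA replication genes 1 rose and 12 fell (1 and 14 adjusted over the list alone; camera adjusted p = 0.00453). Of 17 primitive endoderm markers 0 rose and 6 fell (0 and 7 adjusted over the list alone; camera adjusted p = 0.00929). These also had an adjusted p = 0.520 with an estimated correlation.

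Blastocyst MZ_KO against M_KO compared groups that share the title prefix C7, so the prefix does not separate them. Enpep fell from 121 ± 22.3 to 3.69 ± 3.46 CPM (−5.13, SE 0.50, adjusted p = 7.63e-06). Gfm1 fell from 171 ± 32.7 to 5.82 ± 7.09 CPM (−5.33, SE 0.53, adjusted p = 9.23e-06). Fabp5 fell from 167 ± 55.9 to 7.47 ± 2.68 CPM (−4.30, SE 0.27, adjusted p = 4.37e-08) and Ndrg1 by 3.94 (SE 0.56, adjusted p = 2.77e-04; SD, n = 4 and 3). Clec10a rose from 15.97 ± 8.06 CPM (2.82, SE 0.56, adjusted p = 0.00406) and Actn2 from 47.1 ± 18.4 CPM (2.12, SE 0.34, adjusted p = 6.71e-04). B2m rose from 79.0 ± 23.1 CPM (2.09, SE 0.35, adjusted p = 9.97e-04) and Fstl3 from 41.2 ± 14.5 CPM (1.87, SE 0.34, adjusted p = 0.00234). Eomes fell from 232 ± 67.2 to 48.0 ± 13.3 CPM (−2.24, adjusted p = 0.00190). In blastocyst MZ_KO against M_KO 358 genes were higher and 775 lower. The count of 1133 fell to 726 without MZ_KO 2 and to 727 without M_KO 1, the shallowest blastocyst library. Oviduct markers took 0.144% ± 0.0212 of reads in MZ_KO and 0.184% ± 0.0195 in M_KO (exact permutation p = 0.0286, the smallest possible, SD, n = 3 and 4). MZ_KO 6 had 0.126% with the oviduct gene Ovgp1 at only 0.0459 CPM, so this share does not show how much oviduct RNA a blastocyst carried. Granulosa markers took 0.220% in M_KO 3 and 0.108% in M_KO 5, above every MZ_KO embryo (at most 0.0765%).

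Sets were called as follows in blastocyst MZ_KO against M_KO. Of 78 cytosolic ribosomal proteins 18 rose and 0 fell (32 and 1 adjusted over the list alone; camera adjusted p = 1.93e-14, and adjusted p = 0.519 with an estimated correlation), with a summed share of 3.87% ± 0.357 against 3.21% ± 0.166 of reads (exact permutation p = 0.0286, SD, n = 3 and 4). Of 37 proteasome genes 3 rose and 2 fell (3 and 2 adjusted over the list alone; camera adjusted p = 9.95e-04, and adjusted p = 0.603 with an estimated correlation). Of 77 mitochondrial ribosome genes 3 rose and 2 fell (1 and 2 adjusted over the list alone; camera adjusted p = 0.0152, and adjusted p = 0.699 with an estimated correlation). Of 13 nutrient transporters 0 rose and 4 fell (0 and 8 adjusted over the list alone; camera adjusted p = 0.00243, and adjusted p = 0.102 with an estimated correlation), including Slc2a1 (−2.26, adjusted p = 0.00332) and Slc16a1 (−1.19, adjusted p = 6.10e-04). Of 41 DNA replication genes 1 rose and 12 fell (1 and 15 adjusted over the list alone; camera adjusted p = 8.58e-04). Of 23 fatty acid oxidation genes 0 rose and 3 fell (0 and 4 adjusted over the list alone; camera adjusted p = 0.0396), with Acaa2 at −1.47 (adjusted p = 1.02e-05). Both had an adjusted p = 0.448 with an estimated correlation.

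Blastocyst M_KO against WT_flfl gave 0 genes past the threshold by limma, 494 of 9585 at an unadjusted p under 0.05 and 0 by limma-voom. Ctcf had a log2 fold change of −0.47 (SE 0.23, adjusted p = 0.937). Eomes (0.59, adjusted p = 0.968), Nanog (0.21, adjusted p = 0.975) and Cdx2 (0.10, adjusted p = 0.991) did not pass either. Without any called gene, the sets of mitochondrially encoded transcripts (camera adjusted p = 0.00257) and p53 targets (0.0119) were lower, and those of the proteasome (0.0119), the mitochondrial ribosome (0.0166), granulosa markers (0.0166) and epiblast markers (0.0442) were higher. Adjusted over the list alone, 3 of 8 granulosa markers were higher, 1 of 23 p53 targets was lower and 0 genes of the other sets passed. These had an adjusted p = 0.778 with an estimated correlation for the p53, granulosa and epiblast sets and an adjusted p = 0.942 with an estimated correlation for the others. Under quantile normalization the proteasome (0.127), mitochondrial ribosome (0.0600) and epiblast (0.0600) calls were lost. Cyp11a1, a steroid enzyme of granulosa cells that the trophectoderm list also holds, averaged 262 ± 362 CPM in M_KO against 1.86 ± 3.02 CPM in WT_flfl (SD, n = 4 and 3), led by M_KO 3 (778 CPM) and M_KO 5 (247 CPM). These groups differ in prefix as well as in label.

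Blastocyst het against WT_flfl also gave 0 genes by limma, 187 of 9585 at an unadjusted p under 0.05 and 0 by limma-voom, within the prefix N89. The log2 fold change of Ctcf was −0.50 (adjusted p = 0.999). Sets of cytosolic ribosomal proteins (camera adjusted p = 8.73e-13), oxidative phosphorylation (7.18e-08), the proteasome (2.59e-04), the mitochondrial ribosome (0.00872) and DNA replication (0.0412) were lower, with an adjusted p = 0.810 with an estimated correlation. The summed share of cytosolic ribosomal proteins, 2.88% ± 0.334 against 3.15% ± 0.117, did not pass (exact permutation p = 0.286, SD, n = 4 and 3). Mitosis genes were higher as a set (camera adjusted p = 2.75e-07, and adjusted p = 0.184 with an estimated correlation). No member of these sets passed, and 0 did adjusted over the list alone. The proteasome and DNA replication calls were lost under quantile normalization (0.116 each).

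Morula MZKO against het asks for the effect at the earlier stage, where 41 of 9953 genes were higher and 7 lower. Zswim5, a zinc finger protein gene, rose from 5.79 ± 6.48 to 223 ± 90.5 CPM (5.51, SE 0.65, adjusted p = 1.04e-04; chromosome 4, 116877376 to 116989264). Impact, an imprinted regulator of translation, rose from 13.9 ± 7.28 to 113 ± 32.2 CPM (3.04, SE 0.39, adjusted p = 2.90e-04; chromosome 18, 12955852 to 12992950), and the kinase Taok1 from 52.8 ± 12.01 to 255 ± 83.8 CPM (2.21, SE 0.31, adjusted p = 9.96e-04). The amino acid transporter Slc38a6 rose by 2.43 (SE 0.36, adjusted p = 0.00148). Sfn, which encodes 14-3-3 sigma, fell from 1034 ± 359 to 262 ± 75.2 CPM (−1.96, SE 0.29, adjusted p = 0.00148), and Mrps2 fell from 112 ± 3.44 to 10.2 ± 5.43 CPM (−3.69, SE 0.68, adjusted p = 0.0111; SD, n = 3 and 6), a call lost without het 1, het 5 or het 7 (adjusted p = 0.0507, 0.0638 and 0.0843). Cdx2 (−2.00, adjusted p = 0.388), Gata3 (−3.22, adjusted p = 0.114) and Nanog (1.65, adjusted p = 0.170) did not pass, nor did Ctcf (−3.23, SE 0.90, adjusted p = 0.169), which passed at a pseudocount of 5 (−2.27, adjusted p = 0.0319). The count of 48 was 234 with weights per embryo, 74 under quantile normalization, 25 with the Y-linked level as covariate, 24 by limma-voom, 25 without pseudogenes, 29 without het 7 and 87 without MZKO 1. Y-linked genes were expressed in 0 of 3 het but in 3 of 6 MZKO embryos. MZKO 1 and het 1 had more oviduct RNA (0.708% and 0.322% of the scaled library size) and haemoglobin RNA (0.402% and 1.52%) than the other embryos of their groups. MZKO carries the prefix C50 and het N2, so prefix and group coincide.

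Annotated pseudogenes made up 14 of the 48 genes, and the change of mt-Nd3 belongs with them. mt-Nd3, a mitochondrially encoded subunit of complex I (chromosome M, 9459 to 9806), stood at 211 ± 79.5 CPM in MZKO, 17.2 ± 9.88 CPM in del and 11.3 ± 1.70 CPM in het (MZKO against het 4.02, SE 0.43, adjusted p = 3.97e-05). Gm28438, a copy in the nuclear genome (chromosome 1, 24612775 to 24613119), stood at 0.315 ± 0.772, 226 ± 126 and 154 ± 32.9 CPM (SD, n = 6, 4 and 3). The copies match at 344 of 345 aligned bases and differ by T3C, the base of mt-Nd3 first, the position counted from 1 at the 5′ end of its transcript, then the base of Gm28438. The summed level was 211 ± 79.3, 243 ± 134 and 166 ± 34.1 CPM, and MZKO and het did not differ in it past the threshold (log2 difference 0.28, exact permutation p = 0.440). Neither gene's change on its own is therefore certain.

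Of gene sets in morula MZKO against het, oxidative phosphorylation (camera adjusted p = 5.48e-09, 0 of 75 members called), cytosolic ribosomal proteins (4.79e-07, 0 of 78 called) and the mitochondrial ribosome (3.55e-04, with 1 higher and 1 lower of 76) were lower, and mitochondrially encoded transcripts (7.03e-04, with mt-Nd3 higher of 15) were higher. The summed share of cytosolic ribosomal proteins was 4.44% ± 0.891 in MZKO and 5.56% ± 1.86 in het (exact permutation p = 0.25, SD, n = 6 and 3), which did not pass. Adjusted over the list alone, the members called were the same in number. These 4 sets had an adjusted p = 0.997 with an estimated correlation. Ndufb8 of complex I had a log2 fold change of −0.995 (adjusted p = 0.171) and Rpl3 of the large ribosomal subunit −0.83 (adjusted p = 0.2502, and 0.0333 under quantile normalization). Summed with its copy Rpl3-ps1, a pair chosen after its values were seen, Rpl3 had a log2 difference of −0.23 (exact permutation p = 0.452).

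Morula MZKO against del compared groups whose Ctcf levels did not differ past the threshold and whose prefixes differ. There 14 genes were higher and 4 lower. Rpl3-ps1, a processed copy of Rpl3 (chromosome X, 13202571 to 13203780), stood at 572 ± 189.7 CPM against 0.337 ± 0.674 CPM (adjusted p = 4.51e-10), and Gm10093 at 217 ± 70.8 CPM against 0 CPM (adjusted p = 1.07e-08), so that both fitted changes depend on the pseudocount. mt-Nd3 rose by 3.62 (SE 0.39, adjusted p = 3.56e-05) and Zswim5 from 14.2 ± 11.2 to 223 ± 90.5 CPM (4.16, SE 0.59, adjusted p = 0.00126; SD, n = 4 and 6). Annotated pseudogenes made up 10 of the 18 genes, and 6 were called without pseudogenes. The count was 42 with weights per embryo, 10 under the stricter filter and 2 by limma-voom. The pairs of Rpl3-ps1 with its parent Rpl3, Gm10093 with Hdac1, and mt-Nd3 with Gm28438 were chosen after their values were seen. None differed past the threshold in its sum (log2 differences 0.11, 0.071 and −0.16, exact permutation p = 0.586, 0.719 and 0.705). Rpl3 and Hdac1 made up most of their sums (1496 and 877 CPM in del), with 572 and 217 CPM for their copies in MZKO. The sums of these pairs respond weakly to the copy and cannot tell a real rise of it from reads assigned differently. Of the stretches of 30 bases in Rpl3-ps1, Gm10093 and Gm28438, 94.9%, 86.5% and 99.1% also occur in Rpl3, Hdac1 and mt-Nd3. The changes of Rpl3-ps1, Gm10093 and mt-Nd3 on their own are therefore not certain. Lower as sets were cytosolic ribosomal proteins (camera adjusted p = 4.29e-06), the mitochondrial ribosome (5.67e-04), oxidative phosphorylation (0.0182) and ribosome biogenesis (0.0352). Higher were glycolysis (0.00364), primitive endoderm markers (0.0352) and oviduct markers (0.0352). No member of these sets passed, and 0 did adjusted over the list alone. MZKO 1 had 0.708% oviduct RNA, the most of the MZKO embryos. The summed share of cytosolic ribosomal proteins, 4.44% ± 0.891 against 5.08% ± 0.704 in del, did not pass (exact permutation p = 0.262, SD, n = 6 and 4). All 7 sets had an adjusted p = 0.922 with an estimated correlation, and quantile normalization ended the calls of oxidative phosphorylation (0.0720), ribosome biogenesis (0.0974) and primitive endoderm (0.0583).

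Morula del against het, within the prefix N2, gave 1 changed gene. Adprhl2 stood at 1.75 ± 2.82 CPM in del against 62.6 ± 26.7 CPM in het (−4.89, SE 0.75, adjusted p = 0.0318; SD, n = 4 and 3), a value that depends on the pseudocount, and the call was lost without del 2, del 4, del 6, het 5 or het 7 (adjusted p = 0.123, 0.113, 0.102, 0.219 and 0.253). At an unadjusted p under 0.05 there were 503 genes, and limma-voom called 0. The count of 1 was 10 with weights per embryo, 3 under quantile normalization and 4 without MZKO 1 and het 1. Cdx2 (−2.81, adjusted p = 0.630), Gata3 (−3.20, adjusted p = 0.629) and the keratin Krt8 (−2.21, adjusted p = 0.774) did not pass. Lower as sets were oxidative phosphorylation (camera adjusted p = 0.00126), trophectoderm markers (0.00469), immediate early genes (0.00620), blood markers (0.0126) and primitive endoderm markers (0.0413), and mitochondrially encoded transcripts were higher (0.00132), all with an adjusted p = 0.953 with an estimated correlation. No member passed over all genes. Adjusted over the list alone, 2 of 25 trophectoderm markers, 2 of 14 immediate early genes and 4 of 11 blood markers were lower and 0 members of the other sets passed. Haemoglobin RNA took more reads in every het embryo (1.52%, 0.0389% and 0.0710% in het 1, het 5 and het 7) than in any del embryo (at most 0.00903%; exact permutation p = 0.0286, the smallest possible, n = 3 and 4).

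The MZ knockout effect against het was also compared between the stages by a test of the difference itself, blastocyst minus morula, over 8572 genes. For Fstl3 the difference was 2.69 (SE 0.49, adjusted p = 0.00364), for the trafficking gene Vps51 2.12 (SE 0.41, adjusted p = 0.00679) and for Tmem159 1.86 (SE 0.36, adjusted p = 0.00552), the blastocyst effect being the higher. For Gfm1 it was −4.53 (SE 0.73, adjusted p = 0.00120), for Adprhl2 −4.69 (SE 0.69, adjusted p = 4.62e-04) and for Gata4 −5.33 (SE 0.93, adjusted p = 0.00292), with Adprhl2 and Gata4 near 0 reads in MZ_KO and dependent on the pseudocount. Impact differed by −3.39 (SE 0.63, adjusted p = 0.00470). The test called 54 genes with a higher and 84 with a lower blastocyst effect, and limma-voom called 160. Leaving out morula het 1, the morula with most haemoglobin RNA, raised the count of 138 to 708 and leaving out MZKO 1 raised it to 220. It fell to 74 without blastocyst MZ_KO 2, 57 without MZ_KO 6, 82 without het 3, 91 without het 5, 67 without het 6, 85 without morula het 5 and 53 without morula het 7. For this difference of the MZ knockout effect between stages it was 715 with weights per embryo, 65 with the Y-linked level as covariate, 61 without blastocysts WT_flfl 1 and het 6, and 761 without morulae MZKO 1 and het 1. Y-linked genes were expressed in 0 of 3 morula het but 3 of 4 blastocyst het embryos. Quantile normalization moved the split to 143 higher and 112 lower, or 56.1% instead of 39.1% higher. Stage and sequencing batch coincide, and each effect was taken within its own table.

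Sets with a higher blastocyst effect were cytosolic ribosomal proteins (camera adjusted p = 4.96e-22, with 1 higher and 0 lower of 78, and 32 and 0 adjusted over the list alone), the mitochondrial ribosome (1.11e-09), oxidative phosphorylation (4.65e-06, with 9 higher and 1 lower adjusted over the list alone) and the proteasome (4.65e-06). Sets with a lower blastocyst effect were mitochondrially encoded transcripts (1.29e-04), DNA replication (0.00106), glycolysis (0.0279), mitosis (0.0308) and primitive endoderm markers (0.0383). Lower members adjusted over the list alone numbered 2 of 15, 7 of 41 (with 1 higher), 3 of 17, 0 of 44 and 2 of 14 in that order, against 1, 0, 1, 0 and 1 over all genes. There was an adjusted p = 0.788 with an estimated correlation for mitosis and an adjusted p = 0.585 with an estimated correlation for the others. In morulae, reads of Rpl3 and of mt-Nd3 could be assigned to near-identical copies, and no set was tested without such genes.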

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

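The test of pseudogenes among the called genes, the test of summed mt-Nd3 and Gm28438 levels, the second draw of splits, the test of blood RNA in het 6 and the test of del beside the second pattern were chosen only after the results were seen, the other explanations below were set down before their tests, and the wording of the Ctcf explanation was narrowed to blastocysts afterwards with its bounds kept.

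Single embryos stood apart from their group by a gap to the nearest embryo that was large against the group's whole range, in 5 of 96 groups of values tested (5.21%, where chance alone gives about 1 in 20). Morula del 6 had 1635553 reads against 12368954 to 13923394 in the other del embryos. Morula MZKO 1 had 0.402% haemoglobin RNA and 0.708% oviduct RNA, against at most 0.130% and 0.0921% in the other MZKO embryos. Puromycin stood at 20.5 CPM in blastocyst M_KO 3, against 8.25 to 10.02 CPM in the other M_KO embryos. Mrps2 stood at 0.236 CPM in morula MZKO 8, against 8.50 to 15.8 CPM in the other MZKO embryos.

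A signal outside the genes tested was LacZ, at 83.1 CPM in MZ_KO, 25.7 CPM in M_KO and 28.0 CPM in het blastocysts, above the 0.543 CPM of WT_flfl.

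The MZ knockout effect against het differed between the stages for 138 genes by the test of the difference itself. Blastocyst minus morula, the log2 differences of the genes named for their size, which asked for a mean of at least 100 CPM in MZ_KO or het blastocysts and no overlap of these groups and so left out Gata4 and Impact, were 2.69 for Fstl3, 2.53 for Rab29, 2.12 for Vps51, 1.98 for Gemin7, 1.86 for Tmem159, 1.84 for Gpr137b, −4.69 for Adprhl2, −4.53 for Gfm1, −3.65 for Alpl, −2.93 for Fabp5, −2.81 for Tubb5 and −2.71 for Got2. Leaving out 1 embryo ended the calls of Rab29, Tubb5 and Got2 (without morula het 7, adjusted p = 0.0578, 0.0506 and 0.0642), of Gemin7 (without blastocyst MZ_KO 6, 0.0503), of Alpl in 4 such fits (0.0507 to 0.0614), of Gpr137b in 7 (0.0505 to 0.118) and of Fabp5 in 9 (0.0508 to 0.104). Of 100 drawn splits, 1 gave as many genes, the real one, with 102 as the highest count of the others. A second draw of 100, with the embryos in another order, gave 2 as large, the real one and a split with 479 genes. Both shares are under 0.05, but 479 genes from another split point to a structure of the samples apart from the labels. The count by itself therefore cannot tell an effect of the labels from that structure. Stage and sequencing batch cannot be told apart.

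The first pattern is the large set of genes called in MZ_KO blastocysts. Against WT_flfl 1 of 10 splits gave as many genes as the labels (1265, highest other 0). That is too few splits for a share under 0.05. Against het 1 of 35 splits did (1711, highest other 349) and against M_KO 1 of 35 (1133, highest other 266). A share of 0.0286, the smallest possible there, makes chance unlikely but does not exclude it, since 9 comparisons were tested this way. Against het, prefix and label coincide, so the splits cannot tell them apart. A difference between the title prefixes C7 and N89 would show in M_KO against WT_flfl too, unless the M_KO label offset it. The M_KO change was a median share of only 0.168 of the MZ_KO change (interquartile range 0.0249 to 0.326). Choosing genes by the MZ_KO change lowers this share by itself, and the WT_flfl embryos common to both changes raise it. M_KO against WT_flfl called 0 of 9585 genes, while MZ_KO against M_KO, within the prefix C7, called 1133. These counts argue against the prefix as the cause of most of the pattern. Without WT_flfl 1 and het 6, which had much blood RNA, the median share of the change left was 1.01 against WT_flfl (interquartile range 0.954 to 1.08), where WT_flfl 1 takes part. It was 0.965 against het (0.910 to 1.02), where het 6 does. Genes called with these embryos included tend to be alike over their group, so a high share says little against blood RNA. The counts of called genes fell without these embryos, where fewer embryos were fitted. MZ_KO against M_KO compares neither embryo, so its 1133 calls do not rest on their levels, although both entered its filter and variance. That comparison cannot test blood RNA as a source of the calls against WT_flfl and het, for which it stays open. Loss of Ctcf stays open as a hypothesis, as do other differences between the parents or collection of these embryos, which were not tested.

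The second pattern is the set of genes called higher in morula MZKO against het. The labels gave 48 called genes, and 2 of 84 splits gave as many, a share under 0.05. Another split gave 676, MZKO 2, 3, 4 and 6 with het 5 and 7 against MZKO 1, MZKO 8 and het 1, which points to a structure of the samples apart from the labels. MZKO 1 and het 1 had the most oviduct and haemoglobin RNA of their groups. The count by itself therefore cannot tell an effect of the labels from that structure. Over the 26 higher genes that were tested in blastocysts, the median log2 fold change of MZ_KO against M_KO was 0.048 (interquartile range −0.10 to 0.36) against 2.03 in morulae. For these 26 genes, this argues against an effect of the low Ctcf level of MZ_KO, which M_KO does not share, acting alike in blastocysts. An effect of a lost maternal store would cancel in this comparison if M_KO shares that loss. Such an effect stays open, as does one limited to morulae. Annotated pseudogenes were 12 of the 41 higher genes (29.3%) but 251 of the 9953 tested (2.52%; Fisher's exact test, two-sided p = 2.10e-10), so reads divided differently between copies may account for part of the pattern. Of the 41 higher genes, 12 were also called higher in MZKO against del, which has little Ctcf too but the prefix of het. Most of these are processed pseudogenes, and mt-Nd3 is among them. In del against het 11 of them stood at log2 values of −0.13 to 0.40, but at 3.62 to 8.78 in MZKO against del (Zswim5 at 1.35 and 4.16). The median del share of the MZKO change was 0.0195. Choosing genes for a large difference from del lowers this share by itself, so it cannot test the Ctcf level. The prefix, or another difference between MZKO and del, stays open for these genes. Over all 41 the median was 1.19 in del against het (interquartile range 0.40 to 1.44) and 2.47 in MZKO against het, both relative to the het embryos they were chosen against. For the other 29 genes the prefix and loss of Ctcf both stay open, since these did not pass in MZKO against del and del against het uses the het embryos they were chosen against.

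The third pattern is mt-Nd3 higher and Gm28438 lower in morula MZKO against het. The summed CPM of both genes differed by a log2 value of 0.28 against 4.02 for mt-Nd3 alone, which is consistent with the same reads being assigned to one copy or the other. The copies share 313 of 316 words of 30 bases (99.1%). A mitochondrial sequence variant between embryos of the prefixes C50 and N2 may set the assignment, as may the processing, and neither was tested. No biological explanation was tested for this pattern.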

How the results depend on the processing

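The log2 values as deposited, limma-voom, the weaker filter, the block on column numbers and leaving out pseudogenes or embryos with much haemoglobin RNA were chosen after the data were seen, and the remaining alternatives were planned. Each count below is of genes at an adjusted p under 0.05, and the cause of a change was not tested unless fewer embryos or genes were fitted. All 9 counts stayed within 1.5 times at a pseudocount of 5, and of 271 named called genes 267 kept their call there and 259 under quantile normalization, while single left-out embryos ended such a call in 243 fits and kept it in 1713. The count of blastocyst MZ_KO against WT_flfl (1265) ranged from 783 (without WT_flfl 7) to 1153 over single left-out embryos, was 787 without WT_flfl 1 and het 6, and 2071 against the mean of WT_flfl and het. That of blastocyst MZ_KO against het (1711) ranged from 1072 (without MZ_KO 2) to 1603 and was 1013 without WT_flfl 1 and het 6. That of blastocyst MZ_KO against M_KO (1133) ranged from 726 (without MZ_KO 2) to 1112. Blastocyst M_KO against WT_flfl (0) was 1 with the Y-linked level as covariate and 1 without WT_flfl 1 and het 6, and het against WT_flfl (0) ranged from 0 to 1 (without WT_flfl 1). Other splits of the same embryos gave as many genes in 35 of 35 cases for each of these, as any split does against a count of 0, with highest others of 1 and 5. For morula MZKO against het the count (48) was 74 under quantile normalization, 234 with weights per embryo, 25 with the Y-linked covariate, 24 by limma-voom and 25 without pseudogenes, and ranged from 29 (without het 7) to 87 (without MZKO 1). For morula MZKO against del it (18) was 10 under the stricter filter, 42 with weights, 2 by limma-voom and 6 without pseudogenes. Of 100 splits drawn from the 210 possible, 1 gave as many genes, the real one, with 2 the highest of the others. Chance is therefore unlikely but not excluded, since the splits not drawn could give a higher count, and prefix and label coincide there. For morula del against het it (1) was 0 at a pseudocount of 0.5, with no filter, with the stricter or weaker filter, with the Y-linked covariate, on the log2 values as deposited, by limma-voom and with only the 2 groups fitted, 3 under quantile normalization, 10 with weights and 4 without MZKO 1 and het 1, and ranged from 0 to 3 (without het 1) over left-out embryos. For it 7 of 35 splits gave as many, with 6 the highest of the others, so chance cannot be excluded. For the difference of the MZ knockout effect between stages it (138) was 255 under quantile normalization, 715 with weights, 65 with the Y-linked covariate, 61 without WT_flfl 1 and het 6 and 761 without MZKO 1 and het 1, and ranged from 53 (without morula het 7) to 708 (without morula het 1). Leaving out 1 embryo turned the sign of genes that were never called: Gata6 in blastocyst MZ_KO against WT_flfl (−0.086 without WT_flfl 1, to 0.27), against het (−0.052 without het 5, to 0.40) and against M_KO (−0.014 without MZ_KO 7 and −0.032 without M_KO 3, to 0.18), Kdm5b in blastocyst MZ_KO against WT_flfl (−0.014 without MZ_KO 6, to 0.43) and Cyp11a1 in blastocyst MZ_KO against M_KO (0.039 without MZ_KO 6, otherwise down to −3.11).

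Of the list calls, 56 were made, 47 held under quantile normalization, 15 with fry and 0 with an estimated correlation. The lists that did not pass are given as counts only, a choice made after some were seen to change direction. Of these 205 list results, quantile normalization brought 22 past the threshold and reversed 15, fry brought 19 past it, a pseudocount of 5 brought 4 past it and reversed 5, and an estimated correlation moved 0. The planned count-based alternative was not run, although whole reads could be recovered, and limma-voom on those reads was run in its place. A mean with the second library of blastocyst het 3, which was not analysed here, was not run either. Embryos that share a number across morula groups did not deviate together (correlations of 0.085, −0.120, −0.040 and 0.140, and 1 of 4 del embryos correlated best with its own number), so the number does not pair them. With it as a replicate block MZKO against del gave 14 genes, 12 higher and 2 lower. A block on column numbers left all 5 blastocyst counts within 1.5 times, 1244 for blastocyst MZ_KO against WT_flfl, 1501 for blastocyst MZ_KO against het, 1111 for blastocyst MZ_KO against M_KO and 0 for the others. At the real depths, simulated 2-fold changes of genes with at least 50 CPM in at least 3 embryos were found in 16% of cases for morula del against het (9934 genes) and in 51% for blastocyst MZ_KO against WT_flfl (9504 genes).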

Other observations

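The comparison of the MZ_KO calls with morula del against het, the test of the direction of neighbouring pairs and the further references for slower development were chosen only after the results were seen. The number of neighbouring pairs and the share lower than in M_KO were set down before theirs.

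Some targets of p53, the transcription factor of the DNA damage response, were higher in blastocyst MZ_KO against M_KO, the comparison within 1 prefix, where M_KO levels were low. Cdkn1a, the cell cycle inhibitor p21, rose from 11.5 ± 0.672 to 83.4 ± 13.7 CPM (2.74, SE 0.59, adjusted p = 0.00665), and Mdm2, the ubiquitin ligase of p53, from 38.2 ± 13.6 to 83.3 ± 11.3 CPM (1.16, SE 0.25, adjusted p = 0.00620). The kinase Plk2 rose from 2.89 ± 3.02 to 30.3 ± 12.3 CPM (3.29, SE 0.76, adjusted p = 0.01005; SD, n = 4 and 3). Trp53inp1 rose by 2.28 (SE 0.58, adjusted p = 0.0182), a call lost without MZ_KO 6, MZ_KO 7, M_KO 1 or M_KO 4 (adjusted p = 0.0709, 0.0504, 0.0507 and 0.0506). Of 23 members 4 rose and 1 fell (4 and 1 adjusted over the list alone), and the set as a whole did not pass (camera adjusted p = 0.0635, and adjusted p = 0.590 with an estimated correlation). WT_flfl stood at 45.5 ± 27.9 CPM for Cdkn1a, 76.3 ± 17.1 CPM for Mdm2 and 16.4 ± 15.1 CPM for Plk2 (SD, n = 3), above M_KO in each. Against WT_flfl 0 of the 23 members rose and 2 fell in MZ_KO, and the set was lower in M_KO (camera adjusted p = 0.0119, and adjusted p = 0.778 with an estimated correlation).

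Metabolic and lineage genes also moved in blastocyst MZ_KO against M_KO. Of 75 oxidative phosphorylation genes 0 rose and 11 fell (0 and 11 adjusted over the list alone; camera adjusted p = 0.2498), with Ndufb7 at a log2 fold change of −2.43 (SE 0.19, adjusted p = 5.54e-07). Of 27 genes of pyruvate and the tricarboxylic acid cycle 2 rose and 7 fell (2 and 13 adjusted over the list alone; camera adjusted p = 0.0860), including the cytosolic isocitrate dehydrogenase Idh1 (−1.46, SE 0.19, adjusted p = 1.00e-04). Hand1, a transcription factor of trophoblast giant cells, rose from 3.34 ± 5.57 to 44.5 ± 18.5 CPM (4.13, SE 0.87, adjusted p = 0.00559). Asns fell from 88.5 ± 28.5 to 4.99 ± 1.84 CPM (−3.89, SE 0.49, adjusted p = 9.41e-05), as did Spp1 (−3.24, SE 0.26, adjusted p = 7.04e-07). The Nodal co-receptor Tdgf1 fell from 409 ± 74.6 to 144 ± 57.8 CPM (−1.55, SE 0.25, adjusted p = 6.47e-04).

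A hypothesis was that genes next to each other on a chromosome change together when Ctcf is lost. Of the genes called in blastocyst MZ_KO against M_KO, 137 adjacent pairs of tested genes were both called, against a median of 133 over 10000 shuffles of the calls over positions (permutation p = 0.383). No excess in the number of pairs was seen, but that number says nothing of their direction. Of the 137 pairs 103 (75.2%) had 1 direction. Without 14 pairs of overlapping genes, which can share reads, 89 of 123 (72.4%) did, against a median of 56.9% over 10000 shuffles of the directions over the called genes (permutation p = 2.00e-04). Neighbours that were called may therefore tend to move the same way, and related genes side by side, which can also share reads, were not left out. Whether this comes from loss of Ctcf stays open, since neighbours can also vary together between any embryos, which was not tested.

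Another hypothesis was that MZ_KO blastocysts develop more slowly. Of the genes called lower in blastocyst MZ_KO against M_KO, 83.0% were lower in morula het than in blastocyst M_KO embryos, against 56.1% of all 8572 genes in both tables and 31.9% of the genes called higher. M_KO is the reference of both comparisons, which by itself raises the first share and lowers the last. Against blastocyst WT_flfl and het, which are neither group of this comparison but entered its filter and variance, the shares were 81.1% and 80.6%, with 56.6% and 57.3% for all genes and 35.4% and 33.3% for the genes called higher. The shared reference therefore accounts for little of the gap, but the tables were scaled separately and stage coincides with sequencing batch, so a delay cannot be told apart from an effect of the batch. Genes that are higher in blastocysts could also fall for reasons other than a delay, which these shares cannot tell apart.

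A further hypothesis was that the same genes shift in morula del against het, which shares no embryo with blastocyst MZ_KO against M_KO. Of 1006 genes called there and tested in both, 701 (69.7%) had the same direction in del against het. Among 35 splits of the del and het embryos 3 gave as high a share, the highest other being 69.9% and the median 50%, so chance cannot be excluded and the question stays open.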
